A study of Bombyx mori with 3 samples.

How the data were processed

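Brains of P50 strain larvae were taken on day 3 of the 5th instar, per the labels, from animals fed on mulberry leaves; RNA was extracted with Trizol and libraries were made with an NEBNext Ultra RNA kit. The submitters' processing notes name Trim Galore, HISAT2 and featureCounts, without versions or roles; the genome build, the annotation and the strand setting of the counting are not given in the sources used here. The deposited table of raw counts per gene holds whole numbers, per the file headers 1 column for each of the 3 libraries. The deposited TPM table, scaled by the authors to a sum of 1e+06 per library, holds the same 17072 genes. The gene lengths implied by the ratio of counts to TPM were the same in every pair of libraries for 100% of 12241 genes with counts in all of them, within a relative tolerance of 1e-06 after scaling by the median ratio. Every sample belonged to the group larval brain, so no comparison between groups could be made.

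Gene names came from a reference gene table of assembly ASM3026992v2, used for names and gene classes only: 14943 of 17072 identifiers matched and 2129 did not. In 36 identifiers part of a gene symbol was attached to the gene number, and these were matched by the number. The table gives symbols and synonyms but no protein names, and 1442 protein-coding genes had a symbol other than a locus number. Gene lists were fixed by theme before the data were examined, as were the tests, the alternatives and the rule for named genes. They were then matched by symbol or synonym before any expression value was seen, and 6 members (A1, A2, A4, Tm, AK and P450) were matched from general knowledge of the symbol. Each list therefore holds the named part of its theme, and 4 of the 27 lists had fewer than 3 members and were not tested. Bombyxin, 30K lipoprotein, cuticle protein and other multigene families may share reads between related copies, which was not measured here.

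Levels are the deposited TPM as mean and SD over 3 libraries; a gene was called expressed at 1 TPM or more in every library. For each list the median over members of the mean log2(TPM + 1) was compared with 10000 random lists of the same size drawn from all genes (two-sided, Benjamini-Hochberg over 23 lists, threshold 0.05); differences on this scale understate those of low genes. Nervous system and other-tissue lists were compared by the difference of medians per library and by a permutation of genes with 100000 resamples. Counts were scaled by TMM and dispersions estimated in edgeR 4.0.16 with an intercept-only design, with genes removed that lacked enough counts in all 3 libraries; counts per gene were tested for homogeneity over libraries by chi-square. Variable genes were ranked by genewise dispersion over the trend among genes with a mean count of at least 50. For each list the median log2 deviation of each library from the mean of 3 was taken on log2(CPM + 1) with TMM scaling. The 4-fold gaps between libraries were taken on the same scale, which understates them for low genes. DESeq2 1.42.0 gave alternative size factors and dispersions. Computing used R 4.3.3, Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3.

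Named genes are the 20 with the highest mean TPM, the 4 highest members of each list (8 for the neuropeptide, clock and hormone lists) with up to 2 of those under 1 TPM in every library, first in alphabetical order, and the 10 most variable genes. Some genes that this rule takes are not reported here. Any other gene named was chosen after its values were seen. This holds for PTTH, for the genes that entered the 10 most variable without the low-count filter, and for PPO1, Cop and PBAN where they are named among the genes with a library apart.

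The steps were tested on simulated data. With counts drawn for the real genes at a BCV of 0.1 and no gene changed, the estimated BCV was 0.0992. With 200 of 9333 genes changed in 1 library it was 0.194, while the median genewise BCV was 0.0799. The common BCV can therefore be pulled up by a few very different genes. Of the changed genes, 60% at 2-fold, 96% at 4-fold, 100% at 8-fold and 100% at 16-fold were among the 200 most dispersed. With sampling noise alone, 0 of 10375 genes were called by the chi-square test. Of 100 random lists, 6 passed an unadjusted p of 0.05 at 6 genes and 8 at 20 genes. Of 100 lists of expressed genes raised 8-fold, 99 and 100 passed. The background was all genes, so part of that rate comes from the members being expressed.

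Alternatives covered the TPM threshold, the pseudocount, the scaling, the background, the summary over members, filters on low counts and leaving out each replicate. The planned comparison of genes with and without predicted promoter G-quadruplexes was not run, because no genome sequence was used here.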

Results

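RNA-seq libraries were made from the brains of wild-type silkworm larvae (Bombyx mori, strain P50) on day 3 of the 5th instar, the last larval stage, in which the animal feeds before it spins. The 3 libraries form 1 group and the labels name no contrast, so the comparisons below are between genes within the brain and between the 3 libraries. The series title asks about promoter G-quadruplexes, 4-stranded DNA structures of guanine-rich sequence, and expression that differs by tissue. Other tissues were not analysed here. The deposited gene counts summed to 19843776 in replicate 1, 17935488 in replicate 2 and 23895452 in replicate 3, over the same 17072 genes. Nothing in the labels says that the libraries came from separate sets of animals, so the spread between them, given below as the SD with n = 3, may be partly technical.

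Of the 17072 genes, 9925 (58.1%) reached 1 TPM in every library, and 1471 reached 100 TPM in every library. The number at 1 TPM or more was 10275 in replicate 1, 10475 in replicate 2 and 10513 in replicate 3. A further 1034 genes passed in some libraries but not in others, and 2646 genes had no count in any. A gene with a count of 0 may lie anywhere up to 3 counts, which is 0.151 CPM (counts scaled to 1e+06 per library) in replicate 1, 0.167 in replicate 2 and 0.126 in replicate 3, a limit that covers counting error only. Protein-coding genes took 96.4 ± 0.143% of the counts (SD, n = 3) and long noncoding RNAs 1.40 ± 0.146%.

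The 20 most abundant genes of the larval brain, ranked by mean TPM, were led by LOC692904 (32913 ± 3628 TPM; SD, n = 3) and LOC692416 (27587 ± 3080 TPM), followed by Cyp4g25, which is given with its 3 values below. EF1a, the translation elongation factor that brings tRNA to the ribosome, stood at 10343 ± 509 TPM, and Hsc70-4, a constitutive chaperone, at 10002 ± 376 TPM. Ant, the mitochondrial ADP/ATP carrier, reached 5861 ± 79.5 TPM, the alpha-tubulin Tua1 5089 ± 544 TPM, and Crabp, a cellular retinoid-binding protein, 5073 ± 330 TPM. Tctp was at 4482 ± 292 TPM and the actin gene A4 at 3410 ± 278 TPM. The ribosomal protein genes RpS3Ae, RpS23, RpL10, RpL3, RpS6, RpL23A and RpL5 lay between 3369 and 4902 TPM. LOC101747015 (3733 ± 428 TPM) ranked among them. The 3 genes with locus numbers have no descriptive symbol in the reference used.

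The list of the 20 most abundant genes also held 2 whose libraries stood far apart. Cyp4g25, a cytochrome P450 of the CYP4G family, measured 57.4 TPM in replicate 1, 17071 TPM in replicate 2 and 21774 TPM in replicate 3. CSP3, a chemosensory protein, measured 566, 7208 and 7320 TPM in the same order. Together the 20 genes held 15.8 ± 0.545% of the TPM (SD, n = 3). Their share of the raw counts was 9.39 ± 0.390%; TPM divides by gene length and raw counts do not.

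Neuropeptide and peptide hormone genes were highly expressed as a group. Their 55 matched members had a median of 48.7 ± 9.63 TPM (SD, n = 3), and 46 of them reached 1 TPM in every library. The bombyxins, insulin-like peptides of brain neurosecretory cells, supplied most of the highest members: Bbx-g1 stood at 379.9 ± 26.5 TPM, Bbx-c1 at 326 ± 19.6 TPM, Bbx-a7 at 264 ± 10.99 TPM and Bbx-a8 at 261 ± 26.96 TPM. Bbx-d1 (237 ± 47.8 TPM), Bbx-a2 (237 ± 28.4 TPM) and Bbx-c2 (199 ± 16.8 TPM) were next, and Crz, which encodes corazonin, reached 274 ± 28.6 TPM. PTTH, the brain peptide that drives ecdysone release and which was picked after its value was seen, was at 129 ± 12.4 TPM. Another 8 members stayed under 1 TPM in every library, among them AKH3 and Bbx-b11. The 23 bombyxin genes form a family of related copies that may share reads, which was not measured here; their median was 97.3 ± 9.70 TPM, against 37.5 ± 6.73 TPM for the 32 other members. The list lay 2.76 log2 units above random lists of the same size (random-list test, adjusted p = 0.00092). The unadjusted p of 0.0002 is the smallest that 10000 random lists can give. On CPM, which is not divided by gene length, it lay 1.15 above and no longer passed (adjusted p = 0.55).

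Receptors for these peptides and for amines had a lower median TPM than the peptide genes, a gap that was not tested and was smaller on CPM. The 52 matched G protein-coupled receptors had a median of 4.48 ± 0.336 TPM (SD, n = 3), with 42 at 1 TPM or more in every library. The highest were Akhr, the adipokinetic hormone receptor (32.5 ± 1.31 TPM), FaR (26.0 ± 0.471 TPM), NGR-A24 (22.2 ± 0.392 TPM) and NGR-B1 (19.8 ± 0.802 TPM), while 4 members including NGR-A2 and NGR-A28 stayed under 1 TPM. The list did not differ from random lists (-0.378 log2 units, adjusted p = 0.81), and on CPM it lay at -0.239 (adjusted p = 0.92), against 1.15 for the peptide genes. Against a background of genes at 1 TPM or more in at least 1 library, the difference was -2.45 log2 units and passed (adjusted p = 0.00084).

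**Figure D1:**
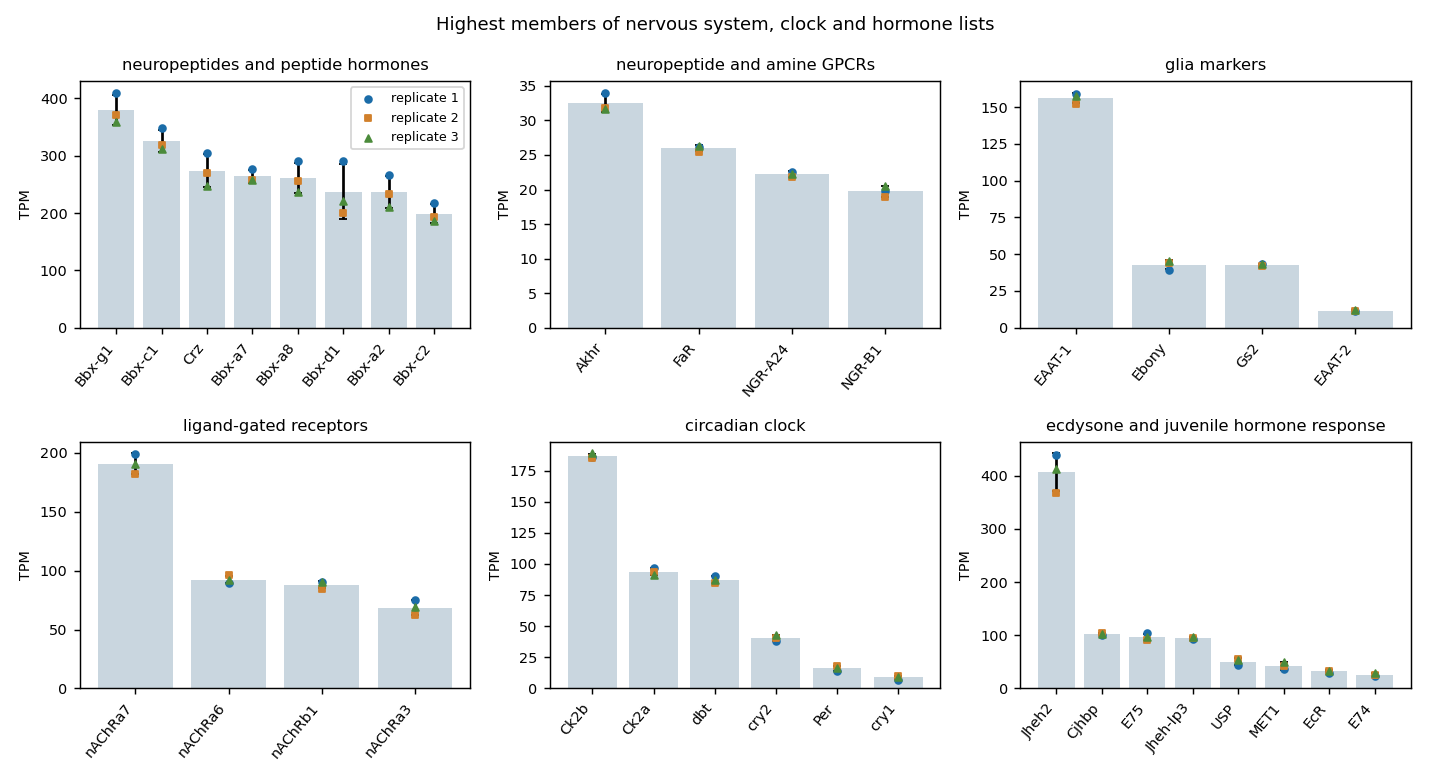
TPM of the highest members of 6 gene lists in larval brain; bars give the mean of 3 libraries, error bars the SD, and points the libraries. The bombyxin genes and Crz lie between 186 and 410 TPM in each library, while the highest receptor for peptides or amines, Akhr, lies between 31.7 and 34.0 TPM.

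Cholinergic genes led the transmitter and receptor lists. Of the 15 matched ligand-gated receptors, 12 were nicotinic acetylcholine receptor subunits, so their lead there follows largely from which genes were matched. The nicotinic acetylcholine receptor subunits nAChRa7 (191 ± 8.88 TPM; SD, n = 3), nAChRa6 (92.5 ± 3.15 TPM), nAChRb1 (88.2 ± 3.24 TPM) and nAChRa3 (68.6 ± 6.37 TPM) were the highest ligand-gated receptors, and the acetylcholinesterase gene ace1 was at 105 ± 6.21 TPM. Of the 15 ligand-gated receptor genes 12 reached 1 TPM in every library. The subunits nAChRa9 (0.120 ± 0.0830 TPM) and nAChRb2, which had no count, were among the 3 below it. DAT, the dopamine transporter, was at 28.2 ± 1.94 TPM. Th, tyrosine hydroxylase of dopamine synthesis, measured 13.01, 24.8 and 33.7 TPM in replicates 1, 2 and 3. The medians of the ligand-gated receptors (22.6 ± 1.41 TPM) and of the 6 transmitter genes (26.0 ± 5.30 TPM) did not pass the random-list test (adjusted p = 0.46 and adjusted p = 0.49). Lists with only 2 matched members were not tested: Syti, a synaptotagmin of synaptic vesicles (138 ± 1.95 TPM), and Rab3 (85.1 ± 5.45 TPM), the sodium channel Nav (66.3 ± 6.52 TPM) and the potassium channel sei (33.1 ± 2.01 TPM), and the neuron markers Tau (187 ± 5.90 TPM) and Elav (40.3 ± 2.24 TPM).

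Glial, clock and developmental genes had list medians between 33.5 and 64.0 TPM. Among glial markers EAAT-1, a glutamate transporter, stood at 156 ± 3.60 TPM (SD, n = 3), Ebony at 42.9 ± 2.93 TPM, glutamine synthetase Gs2 at 42.6 ± 0.797 TPM and EAAT-2 at 11.7 ± 0.245 TPM. All 6 matched clock genes were expressed in every library: the kinase subunits Ck2b (187 ± 1.75 TPM) and Ck2a (93.9 ± 3.09 TPM) and the period kinase dbt (87.3 ± 2.85 TPM) lay above cry2 (40.8 ± 2.51 TPM), Per (16.3 ± 2.07 TPM) and cry1 (8.84 ± 1.53 TPM). Among factors of neuroblasts and neural development, SGF3, a POU-domain factor (78.3 ± 15.7 TPM), the Pax6-type factor toy (58.2 ± 4.60 TPM), Ase (37.7 ± 3.85 TPM) and Notch (34.1 ± 3.34 TPM) were highest, and Ash3 stayed under 1 TPM. The list medians were 42.7 ± 1.38 TPM for glia, 64.0 ± 1.24 TPM for the clock and 33.5 ± 3.09 TPM for the 7 developmental factors. None of these 3 lists passed the random-list test (adjusted p = 0.36, adjusted p = 0.11 and adjusted p = 0.38).

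Cell cycle and replication genes stood above random lists drawn from all genes of the table, but did not pass against expressed genes. All 11 members reached 1 TPM in every library, with a median of 69.3 ± 1.14 TPM (SD, n = 3). BmGEMININ, an inhibitor of replication licensing, was at 228 ± 18.9 TPM, the ribonucleotide reductase subunit RnrS at 179 ± 5.84 TPM, the replication clamp Pcna at 174 ± 19.9 TPM and the mitotic kinase Cdc2 at 92.4 ± 6.42 TPM. The list lay 3.27 log2 units above random lists (adjusted p = 0.018). On CPM the difference was 3.40 and did not pass (adjusted p = 0.068). It fell to 1.12 against genes expressed in at least 1 library (adjusted p = 0.097) and to 1.67 against protein-coding genes (adjusted p = 0.053).

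The genes that respond to ecdysone and juvenile hormone, the hormones that time moulting, spanned a wide range. Jheh2, a juvenile hormone epoxide hydrolase, reached 407 ± 35.3 TPM (SD, n = 3), followed by the binding protein Cjhbp (102 ± 2.17 TPM), the nuclear receptor E75 (97.1 ± 6.12 TPM) and Jheh-lp3 (95.0 ± 2.21 TPM). The ecdysone receptor partners USP and EcR stood at 50.7 ± 6.42 and 32.1 ± 2.08 TPM, the juvenile hormone receptor MET1 at 43.0 ± 7.33 TPM and E74 at 26.1 ± 2.25 TPM. Of 26 members 16 reached 1 TPM in every library and 7 stayed under it, including Grf and Jhdk. The list median of 4.87 ± 0.856 TPM did not differ from random lists (adjusted p = 0.87).

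The lists of ribosomal proteins, heat shock proteins and proteins taken to bind or unwind G-quadruplexes stood above random lists. All 80 ribosomal protein genes were expressed, at a median of 1962 ± 176 TPM (SD, n = 3; 8.04 log2 units above random lists, adjusted p = 0.00092). The 13 heat shock genes had a median of 239 ± 15.2 TPM (5.08 above, adjusted p = 0.00092), with Hsp90 at 1710 ± 179 TPM and the small heat shock proteins Hsp19.9 and Hsp20.1 at 963 ± 146 and 792 ± 65.8 TPM. The G-quadruplex list held 4 matched genes, the Y-box protein Ybp (2085 ± 77.6 TPM), Lark (230.2 ± 11.3 TPM), ILF (195 ± 14.0 TPM) and the helicase MLE (107 ± 4.66 TPM), and lay 4.91 above (adjusted p = 0.0038). Whether each of these 4 proteins binds or unwinds G-quadruplexes was not checked here. Oxidative phosphorylation did not pass (median 18.8 ± 4.57 TPM, adjusted p = 0.49). Its 7 nuclear-encoded genes had a median of 218 ± 24.6 TPM, with Atpsyn-beta at 1031 ± 68.2 TPM, cytc at 548 ± 84.3 TPM, Uqcrc2 at 284 ± 18.2 TPM and Ndufa13 at 218 ± 24.6 TPM. The 13 mitochondrially encoded genes had a median of 1.82 ± 0.668 TPM, and ND2 and ND6 stayed under 1 TPM. Any loss of their reads in alignment or counting was not measured here, so these values may understate their RNA. They are 13 of the 20 members, so the list result rests largely on them. Sex determination genes did not pass either (median 79.2 ± 3.91 TPM, adjusted p = 0.36): Psi stood at 257 ± 1.46 TPM, Tra2 at 148 ± 8.90 TPM, Masc at 10.7 ± 2.02 TPM and Dsx at 0.673 ± 0.177 TPM.

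Most markers of silk gland, midgut and fat body stayed under 1 TPM in every library. All 6 silk gland genes stayed under 1 TPM, with the fibroin light chain Fib-l at 0.274 ± 0.211 TPM (SD, n = 3), P25 at 0.202 ± 0.0609 TPM, the fibroin heavy chain FIBH at 0.166 ± 0.0583 TPM and Ser3 at 0.0399 ± 0.0108 TPM. Among 6 midgut genes, 5 stayed under 1 TPM, including the aminopeptidases Apn1, Apn2, Apn3 (0.175 ± 0.0683 TPM) and Apn4, and the sugar hydrolase genes BmMal2 and Suc1 stood at 1.13 ± 1.06 and 0.148 ± 0.0792 TPM. The 6 lipoprotein genes of the 30K family, abundant in fat body and hemolymph, had a median of 0.336 ± 0.0991 TPM. In the same list of 11 genes serpin-1 (420.4 ± 28.6 TPM) and the transferrin gene Tf (79.8 ± 21.2 TPM) were expressed, while Sp2 (2.19 ± 0.370 TPM) and Lp-c23 (1.20 ± 0.650 TPM) were low and LOC101735447 and LP3 stayed under 1 TPM. The list medians, 0.0815 ± 0.0190 TPM for silk gland, 0.0630 ± 0.00574 TPM for midgut and 0.522 ± 0.387 TPM for fat body, did not pass the random-list test at these list sizes (adjusted p = 0.19, adjusted p = 0.19 and adjusted p = 0.38). The mean over members in place of the median put silk gland (adjusted p = 0.010) and midgut (adjusted p = 0.017) below random lists, as did a background of protein-coding genes (adjusted p = 0.048 and adjusted p = 0.040), and length-matched lists did so for silk gland (adjusted p = 0.0037).

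Cuticle and chemosensory genes lay below random lists as groups but held some abundant members. Of 209 cuticle and epidermis genes 69 reached 1 TPM in every library and 111 stayed under it, such as CPFL2 and CPFL3, and the median was 0.314 ± 0.144 TPM (SD, n = 3). The cuticular protein genes CPH27 (559, 3105 and 1410 TPM in replicates 1, 2 and 3), CPR46 (289, 853 and 679.9 TPM), CPR148 (213, 847 and 487 TPM) and CPH14 (82.9, 351 and 818 TPM) were highest, and all were lowest in replicate 1. Of 92 chemosensory genes 66 stayed under 1 TPM, including BmOR-10 and CSP1, and the median was 0.155 ± 0.00322 TPM. CSP3, CSP5 (462, 1569 and 1288 TPM), CSP4 (86.97, 715 and 674 TPM) and the odorant-binding protein Obp6 (158, 789 and 334 TPM) led that list, again with replicate 1 lowest. The lists fell by -2.46 and -2.65 log2 units against random lists (adjusted p = 0.00092 for both). The cuticle call was lost when random lists were matched on gene length (-0.66, adjusted p = 0.19).

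Some genes of the muscle, hemocyte, gland and immune lists were expressed. All 11 genes of the muscle list, of which A1, A2, A4, Tm and AK were matched from general knowledge of the symbol, were expressed, at a median of 62.0 ± 7.41 TPM (SD, n = 3), with A4, the actin gene A1 (2802 ± 1589 TPM), AK, the arginine kinase (1418 ± 133 TPM), and the myosin light chain MLC-2 (1256 ± 756 TPM) highest. That list lay 3.08 log2 units above random lists (adjusted p = 0.046), 5.01 above on CPM (adjusted p = 0.00092) and 4.13 above with the mean over members (adjusted p = 0.00077). Without replicate 1 the difference was 2.90 and narrowly did not pass (adjusted p = 0.059). It fell to 1.63 with length-matched lists (adjusted p = 0.10), to 0.918 against genes expressed in at least 1 library (adjusted p = 0.21) and to 1.42 against protein-coding genes (adjusted p = 0.11), and did not pass there. Without the members matched from general knowledge it was 2.34 and did not pass (adjusted p = 0.38). Whether the call was lost through these members or through the shorter list was not tested. Among hemocyte genes, NimB measured 46.3, 83.7 and 98.6 TPM in replicates 1, 2 and 3, and the prophenoloxidases PPO2 (26.9, 29.6 and 100.2 TPM) and PPO1 (3.14, 4.90 and 22.6 TPM) were highest in replicate 3. Pp had no count. Endocrine gland genes were led by Hmg-s (93.4 ± 20.8 TPM), P450 (48.5 ± 15.4 TPM), Hmg-r (36.9 ± 2.55 TPM) and Cyp306a1 (18.7 ± 4.50 TPM), while Jhamt and Nvd stayed under 1 TPM. Among 19 antimicrobial peptide genes, CecD2 was at 570.1 ± 197 TPM, Llp1 at 40.04 ± 1.90 TPM and Defensin at 37.0 ± 14.1 TPM. The lysozyme gene Lzm measured 1.81, 52.1 and 71.6 TPM in the 3 libraries, and Defensin2 and glv1 were under 1 TPM. The medians of the hemocyte (31.0 ± 25.7 TPM), endocrine (3.89 ± 0.779 TPM) and antimicrobial (3.96 ± 2.59 TPM) lists did not pass (adjusted p = 0.64, adjusted p = 0.81 and adjusted p = 0.78). Antimicrobial genes passed only against genes expressed in at least 1 library, where they lay below (adjusted p = 0.017).

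**Figure D2:**
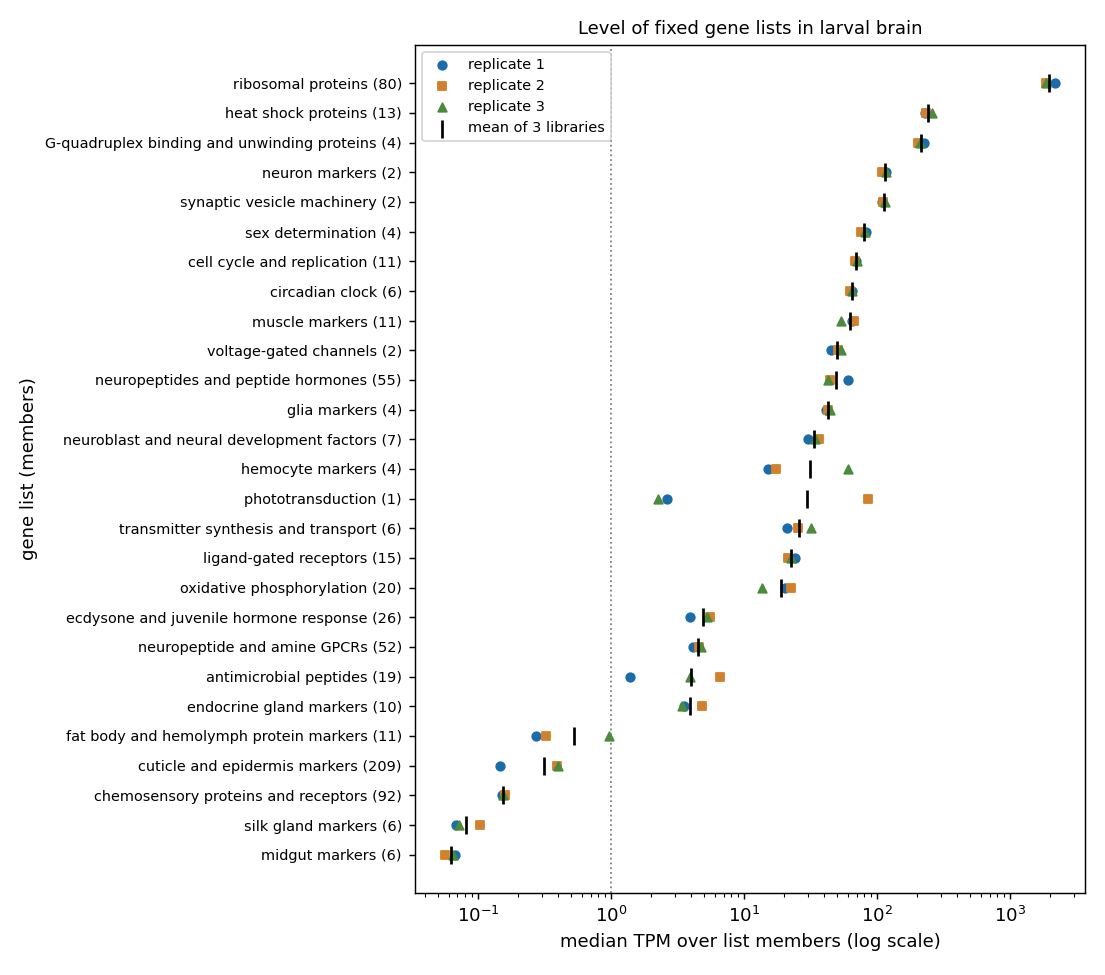
Median TPM over the members of 27 gene lists on a log axis; points give the 3 libraries, vertical bars their mean, the dotted line 1 TPM, and the number of members follows each list name. Ribosomal protein genes lie highest, at 1962 TPM, and midgut markers lowest, at 0.0630 TPM.

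Pooled, the nervous system lists had a higher median than the lists of other tissues, a comparison that depends on which lists enter. The 82 nervous system genes had a median of 41.6 ± 4.14 TPM (SD, n = 3), against 0.388 ± 0.150 TPM for 257 genes of silk gland, fat body and hemolymph, hemocytes, midgut, muscle, cuticle and epidermis, and endocrine glands. The first set had 70 members at 1 TPM or more in every library and the second had 92. The difference of medians was 5.28 log2 units in replicate 1, 4.77 in replicate 2 and 4.78 in replicate 3, a mean of 4.94 ± 0.29. A two-sided permutation of genes between the pooled lists gave p = 1e-05, the smallest that 100000 resamples allow. Genes are not independent replicates, so this p describes these 3 libraries. The design left the 52 peptide and amine receptors out of the nervous system set, and with them the difference was 3.43. The other set is mostly cuticle genes, and without these the difference was 4.05. The muscle list alone, at 62.0 TPM, lay above the pooled nervous system genes.

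Replicates 2 and 3 were closer to each other than either was to replicate 1. The biological coefficient of variation (BCV), the replicate spread beyond counting noise, was 0.134 between replicates 2 and 3, 0.223 between 1 and 2, and 0.222 between 1 and 3. Over the 3 libraries together the common BCV was 0.194. In the simulation a few very different genes pulled this value up, which was not tested on the real counts. The median of DESeq2's fitted trend was 0.114, and the median genewise BCV was 0.0181 between replicates 2 and 3, 0.0678 between 1 and 2, and 0.0658 between 1 and 3. The Pearson correlation of log2(CPM + 1) across genes, which are not independent replicates, was 0.996 between replicates 2 and 3 and 0.990 for both other pairs, with Spearman's rho of 0.982, 0.977 and 0.978 in the same order as the BCV values. Counts of 5841 of 10218 genes (57.2%) departed from sampling noise at an adjusted p of 0.05 (chi-square test of homogeneity, Benjamini-Hochberg). Without replicate 1 the count was 1901 of 10423 genes (18.2%). The chi-square statistic per degree of freedom was 26.0 for the closest pair, so no 2 libraries hold the same counts; this does not show that they came from separate animals.

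The most variable genes were mostly those nearly absent from replicate 1, ranked after a filter that needs enough counts in all 3 libraries. Of the 10 genes with the largest dispersion over the trend, 8 lay between 0.494 and 5.65 TPM in replicate 1 and at 49.7 TPM or more in both others. They were CYP367A1, a cytochrome P450 (0.517, 57.0 and 87.1 TPM in replicates 1, 2 and 3), brP-1649 (5.65, 187 and 286 TPM), LOC101735595 (1.35, 798 and 1011 TPM), LOC101744376 (1.45, 318 and 359.9 TPM), LOC101743396 (1.05, 234 and 340.1 TPM), LOC101735457 (0.900, 172 and 223 TPM), LOC101739690 (0.494, 60.9 and 96.8 TPM) and LOC101741428 (0.770, 49.7 and 79.1 TPM). LOC692643 (4.29, 4.81 and 478 TPM) and ie2 (2.79, 17.0 and 125 TPM) were highest in replicate 3. Only 2 of these 10 stayed among the 10 most variable without replicate 1. Without the filter 7 stayed, and the cuticular protein gene CPR65 (0, 331 and 5.64 TPM), LOC105841510 (0.258, 82.6 and 131 TPM) and LOC101740888 (0.547, 3.75 and 283 TPM) took the places of the other 3.

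**Figure D3:**
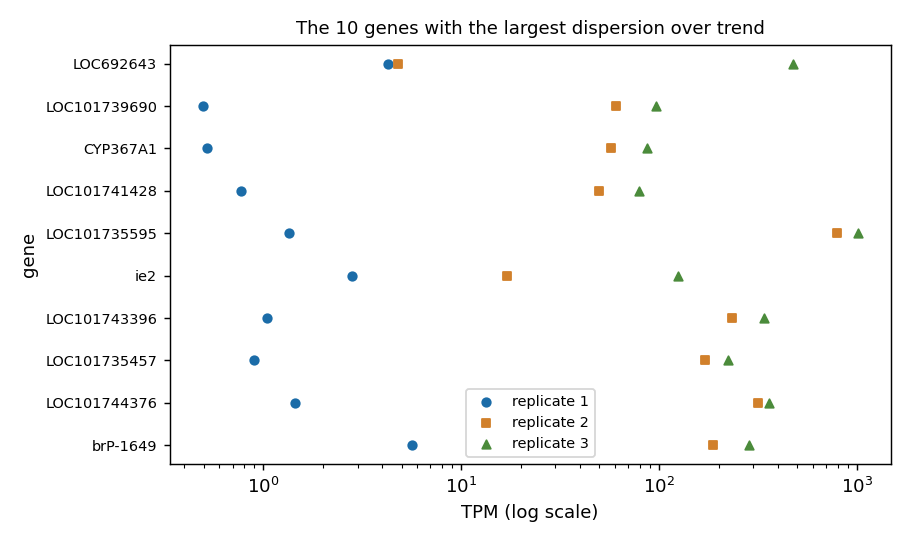
TPM of the 10 genes with the largest dispersion over the trend, on a log axis, with a point for each library. For 8 of them replicate 1 lies at 5.65 TPM or less and both others at 49.7 TPM or more.

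Across 9294 genes with a mean count of at least 50 that also passed the low-count filter, each library had genes at least 4-fold apart from both others on CPM + 1. Adding 1 shrinks the gaps of low genes, so genes 4-fold apart in CPM alone can be missing from these counts. In replicate 1, 58 genes were lower and 0 higher. In replicate 2, 11 were higher and 0 lower, among them Cop, the brain opsin ceropsin and only matched phototransduction gene (2.64, 84.6 and 2.24 TPM), and in replicate 3, 12 were higher and 0 lower, among them PPO1. The filter removes genes nearly absent from a library. Across the 9327 genes with a mean count of at least 50 and no other filter, 77 were lower in replicate 1, 13 were higher in replicate 2 and 16 were higher in replicate 3, with 0 in the other directions. PBAN, a neuropeptide gene picked after its values were seen, was among the last (1.17, 1.34 and 29.999 TPM, from 9, 9 and 265 counts) and was the only member of a nervous system list in these sets. List values after the filter are medians over genes of CPM + 1 divided by its geometric mean over the 3 libraries. On this scale the 52 cuticle genes lay at 0.565 in replicate 1, at 1.40 in replicate 2 and at 1.11 in replicate 3. The 12 chemosensory genes lay at 0.604, 1.35 and 1.18. The 10 muscle genes lay at 0.872, 1.81 and 0.771, and the 3 hemocyte genes at 0.637, 0.703 and 2.26. Endocrine gland genes lay at 0.775, 1.10 and 1.06, antimicrobial genes at 0.766, 1.31 and 1.14, oxidative phosphorylation genes at 1.03, 1.12 and 0.852, and clock genes at 0.979, 1.00 and 0.996. Neuropeptide genes (1.12, 0.971 and 0.934) and ribosomal protein genes (1.11, 0.967 and 0.932) lay at percentile 100 of random lists in replicate 1 and percentile 0 in replicate 3. Lists with larger shifts had similarly extreme percentiles. In replicates 1, 2 and 3 these were 0, 100 and 100 for cuticle, 0, 99.99 and 99.96 for chemosensory, and 0.03, 100 and 0 for muscle genes. Clock genes, at 28.4, 57.3 and 38.1, were not extreme. These are descriptions of single libraries with no test between groups.

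**Figure D4:**
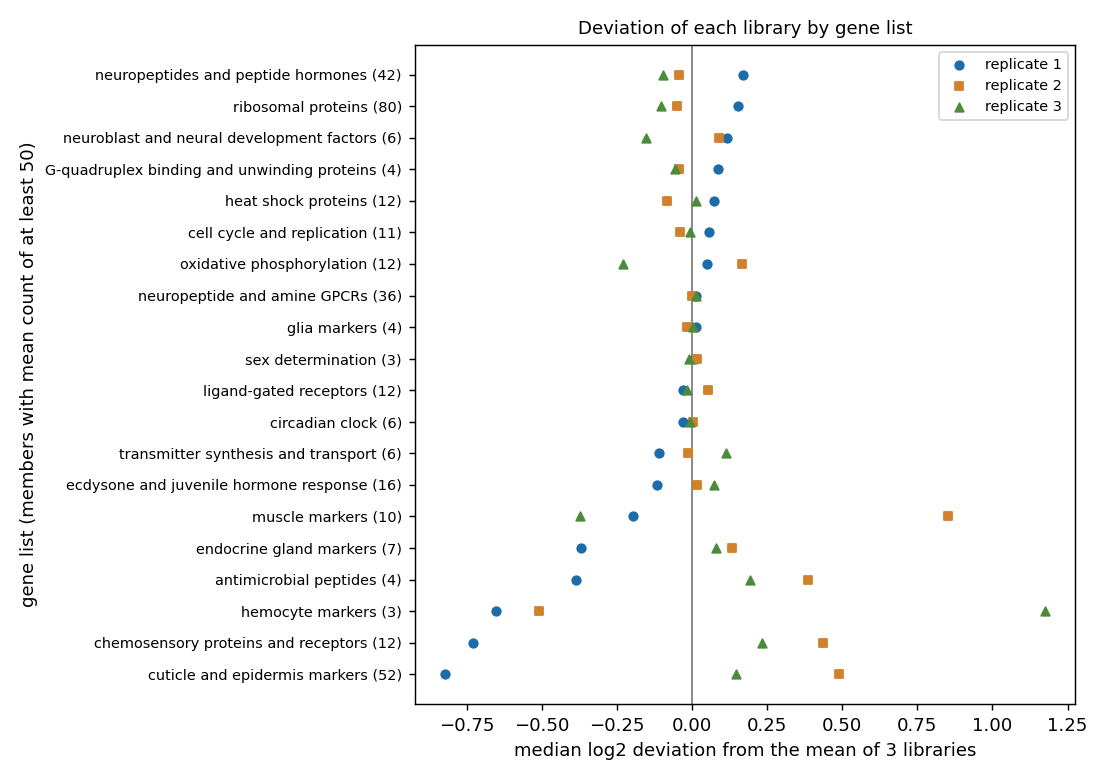
Median log2 deviation of each library from the mean of the 3 libraries, over list members with a mean count of at least 50. Muscle genes lie at 0.85 in replicate 2 and hemocyte genes at 1.18 in replicate 3, while cuticle genes lie at -0.82 in replicate 1.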

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

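The protein-coding background, the addition of peptide and amine receptors, the removal of the low-count filter and the settings without bombyxin genes, without cuticle genes or without the 6 members matched from general knowledge were chosen after seeing the data. No paired analysis was possible because all libraries belong to 1 group. The number of expressed genes stayed between 8493 (at 5 TPM) and 10527 (at 0.5 TPM). The difference between nervous system and other-tissue genes stayed above 0 with permutation p = 1e-05, the smallest possible, in every setting, from 3.06 with expressed members only to 6.47 with a pseudocount of 0.1. The share of the most abundant genes was 15.8% of TPM for 20 genes, 9.39% of raw counts, which are not divided by length, and 11.98% of TPM for 10 genes. The number of lists above random lists went from 6 to 4 against expressed genes, on CPM with either scaling and against protein-coding genes, and to 5 with length-matched lists, without replicate 1 and without the members matched from general knowledge. The number of lists below random lists went from 2 to 4 against genes expressed in at least 1 library, with the mean over members and against protein-coding genes; the cause was not tested. Of 274 values for single lists, 248 kept their direction and side of the threshold, 12 no longer passed and 7 newly passed. Another 7 changed sign, all in lists that passed neither before nor after, and the cause was not tested. Against genes expressed in at least 1 library, transmitter genes went from 1.90 to -0.22 log2 units and oxidative phosphorylation from 1.41 to -0.18, the latter also to -0.21 against protein-coding genes. Hormone response genes went from -0.29 to 0.69 on CPM with either TMM or DESeq2 size factors and to 0.049 with the mean over members, and antimicrobial genes from -0.95 to 1.01 with length-matched lists. The common BCV of 0.194 fell to 0.114 as the median of DESeq2's fitted trend; leaving out each replicate gave 0.134 to 0.223, the lowest without replicate 1. Genes beyond sampling noise numbered 5841, and 1901 to 4999 with a replicate left out, the lowest again without replicate 1. Of the 10 most variable genes, 2 to 9 stayed among the 10 highest with a replicate left out, with 2 without replicate 1, and 6 when ranked by the SD of log2(TPM + 1); the cause of the last was not tested. Without the low-count filter 7 stayed, and the genes 4-fold apart on CPM + 1 rose from 58 to 77, 11 to 13 and 12 to 16 in replicates 1, 2 and 3. Among the lists that passed, leaving out a library ended the call of the muscle list alone, without replicate 1, where the difference went from 3.08 to 2.90 (adjusted p = 0.059, range over its alternatives 0.00077 to 0.38, the highest without the members matched from general knowledge). The silk gland and midgut lists had too few expressed members to be set against expressed genes, and the promoter G-quadruplex alternatives were not run. A count of 0 allows a level of up to 0.167 CPM in the shallowest library, a limit that covers counting error only.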

Other observations

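Gene families picked by symbol after the data were seen, 11 in all, add to the fixed lists. Some members are in both: 1 of the 20 DnaJ genes is in the heat shock list and 1 of the 30 serpins in the fat body list. Cochaperones and tubulins stood high: all 20 DnaJ genes were expressed, at a median of 63.2 ± 0.579 TPM (SD, n = 3), led by DnaJ-9 (290.3 ± 15.9 TPM) and DnaJ-12 (281 ± 17.9 TPM), and the 7 tubulin genes had a median of 199 ± 7.16 TPM, with Tub2 at 3119 ± 313 TPM and Tua3 and Tub4 under 1 TPM. These 2 families passed the random-list test (adjusted p = 0.0055 for both) and the 9 others did not; the DnaJ call is not independent of the heat shock call. Among those, the Argonaute genes of small RNA pathways stood at a median of 113 ± 2.74 TPM (adjusted p = 0.17), with the PIWI protein gene Aubergine at 213 ± 1.87 TPM, Ago2 at 209 ± 3.94 TPM, Ago1 at 15.99 ± 2.79 TPM and Ago3 at 8.90 ± 0.877 TPM. All 10 genes of insulin and TOR signalling were expressed (median 35.5 ± 2.21 TPM, adjusted p = 0.20), with the insulin receptor InR at 47.7 ± 4.64 TPM. The G protein genes and guanylyl cyclases had a median of 33.7 ± 2.69 TPM (adjusted p = 0.24), with Go at 468 ± 44.2 TPM. Of 5 Hox genes only Dfd (3.29 ± 0.464 TPM) was expressed in every library, while Ubx, abd-A and Abd-b stayed under 1 TPM (adjusted p = 0.17).

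Detoxification and immune families held both low and high members. Of 38 UDP-glycosyltransferase genes 18 stayed under 1 TPM (median 0.594 ± 0.167 TPM, adjusted p = 0.17), and of 30 serpins 16 did (0.640 ± 0.199 TPM, adjusted p = 0.17). Among P450 genes outside the hormone lists (2.66 ± 1.06 TPM, adjusted p = 0.73), Cyp9g3 stood at 935 ± 63.7 TPM and Cyp9a19 at 269.8 ± 12.01 TPM with little spread. Cyp4g25, given above, was the highest of these P450 genes by mean TPM and was far lower in replicate 1. Glutathione transferases had a median of 15.5 ± 5.81 TPM (adjusted p = 0.74), with GSTs2 at 753 ± 32.5 TPM. The next highest, GSTd2, measured 92.8, 355 and 350 TPM in replicates 1, 2 and 3. Genes that recognise microbial walls had a median of 3.53 ± 0.960 TPM (adjusted p = 0.73), with PGRP-S1 at 15.6, 76.8 and 64.4 TPM in the same order.

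All tests in this paragraph were chosen after the results were seen. The genes at least 4-fold lower in replicate 1 on CPM + 1, after the low-count filter, numbered 58. Among them were Cyp4g25, Fatp (5.33, 123.9 and 163 TPM in replicates 1, 2 and 3), Dhr-1 (0.368, 18.8 and 24.8 TPM) and the homeobox genes En (0.585, 6.08 and 7.501 TPM) and Inv (0.753, 6.03 and 8.71 TPM). Together the 58 genes held 0.127% of the TPM in replicate 1, 3.11% in replicate 2 and 3.76% in replicate 3. Most of the shares in replicates 2 and 3 came from Cyp4g25 (17071 and 21774 TPM) and CSP3 (7208 and 7320 TPM). The other 2 CYP4G genes had 0 to 6 counts in each library, so the missing Cyp4g25 reads of replicate 1 were not assigned to them. The summed CPM of the 3 CYP4G genes in replicate 1 was 0.0034 of the lower of the other libraries. Reads left uncounted because related copies share them cannot be seen in this sum, so sharing with paralogs stays open. Outer tissue, carrying the 58 genes and the cuticle genes together in the same make-up into replicates 2 and 3, was also tested. The median log2 ratio of replicate 3 to replicate 2 was 0.33 over the 58 genes. Over 48 other cuticle genes it was -0.33, a difference of 0.66 (permutation of genes, p = 1e-05, the smallest possible). Genes are not independent replicates, so this p describes this pair of libraries only. The cuticle genes among the 58 were left out of the cuticle set. Nor did the 58 genes keep 1 ratio among themselves, as their interquartile range of 0.41 lay above all 10000 expression-matched random sets (median 0.18). The 58 genes were chosen for differing between libraries, and the random sets were matched on expression only. The wider range therefore cannot decide on a single cell source of fixed make-up. Over the 77 genes without the filter the difference was 0.664 (permutation of genes, p = 1e-05) and the interquartile range 0.334, at percentile 99.95 of matched sets. A single cell source, several sources, a source whose make-up differed between libraries, and differences between the animals themselves stay open. The sources tested were technical ones, tissue or cells carried in with the brain, and no biological explanation was tested.

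Several muscle genes were higher in replicate 2, with A1 at 1862, 4636 and 1907 TPM in replicates 1, 2 and 3, TpnI at 754, 1818 and 781 TPM, MLC-2 at 889, 2126 and 753 TPM and Kettin at 21.9, 66.4 and 21.1 TPM. The members A4 (3706, 3155 and 3369 TPM), AK (1493, 1496 and 1265 TPM), Tm (65.1, 55.5 and 53.5 TPM) and A2 (5.31, 3.98 and 4.21 TPM) did not share the rise. These members, like A1, were matched from general knowledge of the symbol, and whether they mark muscle was not checked here. The cause was not tested.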
